A study of Mus musculus with 3 samples.

How the data were processed

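Total RNA of wild-type control mouse cortical neurons was extracted on columns and made into libraries with a KAPA kit, per the labels' protocols. The 3 libraries form 1 group and are named replicates 1 to 3 after their titles. Per the submitters' processing notes, the tools were FastQC 0.11.2, STAR 2.5.3a, featureCounts and Subread 1.4.6, with build mm10. The authors deposited 1 table of TPM values for 84660 transcripts of GENCODE mouse release M4, per its name and header. Each TPM column has the same sum, so the values carry relative abundance. The re-analysis of RNA-DNA hybrid data that the design text mentions was not used here.

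Transcripts were matched by identifier without version to GENCODE release M21 on GRCm38, the same build. Of the rows, 98.1% matched, and 1643 did not. In each library, TPM times exonic length was a whole multiple of 1 constant. Whole reads, within 0.01 of a read, came out for 98.0% of 77590 matched rows above 0, and for 97.8% of coding genes' transcripts. The depth so obtained was 32561160, 28734978 and 28283682 reads on coding-gene transcripts. A count of 0 allows up to 3 reads, and such limits cover counting error only. No other sample's columns were used.

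The reads of overlapping transcripts of a gene were not separate. In 1309 of 1309 transcript pairs with 1 nested in the other, the inner had no more reads than the outer, and 96.2% of the inner transcripts had at least 50% of the outer's read density. Values therefore could not be added over transcripts without counting reads repeatedly. The gene value had been planned as the sum over transcripts. It was replaced, after this was seen in the data, by the coding transcript with the most reads, and the planned sum was kept as an alternative. The share of a gene's value carried by 1 isoform, also planned, was not computed for the same reason. Counting used strand: 27 transcripts inside exons of genes on the other strand stood at a median 0.081% of the host's TPM, against 103% for 16 on the same strand.

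Uniqueness was measured on GRCm38 by searching 50-mers, taken every 10 bases of each gene's transcript, on both strands of 22 chromosomes. Of 18227 coding genes with a value, 16047 had at least 90% unique 50-mers and 185 had under 20%. This was done after genes at 0 were seen.

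Levels were compared as log2(TPM + 0.1) differences inside each library, which understate differences of low genes. They are given as mean and SD over 3 libraries with a two-sided exact sign-flip permutation test. A gene with a mean of at least 1 TPM was called expressed. Lengths run between the outermost annotated ends, with classes divided at 10, 30, 100 and 200 kb. The 11 marker lists and 21 functional lists came from textbook knowledge. List medians were ranked among 10000 random lists of coding genes. Replicates were compared by correlation across genes, and no 2 columns were identical. Named are the topoisomerase list, the maturation pairs, the 3 highest members and the lowest of every other list, the 6 highest genes over 200 kb, the 3 highest under 10 kb, the 5 highest coding genes and the 6 with the largest spread. This rule and the lists were fixed before the data were examined. Some genes it names, and 1 maturation pair with its alternatives, are not reported here. Other genes named were chosen after their values were seen.

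The alternatives tried were pseudocounts of 1 and 0.01, the most abundant transcript, rescaling to nuclear coding genes, leaving out each replicate, a minimum of 1 TPM, other length definitions and other thresholds. Alternatives added after seeing the data were genes with at least 90% unique 50-mers and transcripts with whole reads. The statistics were tested on simulated data with known answers. Over 19832 simulated rows, 100% of the reads were recovered, and a planted length class difference of 2 log2 units came out as 2.04 over 18000 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.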

Results

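RNA from wild-type mouse cortical neurons was sequenced in 3 control libraries, which form 1 group. The series title places them in a study of how DNA supercoiling spreads and which topoisomerases act in the neuronal genome. With 1 group there was no comparison between conditions, so the comparisons are between genes and gene groups inside each library. Values are in TPM, a length-scaled relative abundance, and each gene is represented by its coding transcript with the most reads. That choice was made after the data were seen, in place of a planned sum over transcripts. The TPM of a library add up over all 84660 transcripts, which share reads. Values of 1 transcript per gene are therefore lower than TPM scaled over genes, and the minimum of 1 TPM is on this scale. The libraries held 32561160, 28734978 and 28283682 reads on the coding transcripts used. Errors are SD over the 3 libraries. Nothing in the labels says that they came from separate cultures, so this spread may in part be technical. With 3 libraries the smallest p that the two-sided exact sign-flip test allows is 0.25, so no difference could reach 0.05.

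The first question was which topoisomerase genes these neurons expressed. Top2b, the type II enzyme of postmitotic cells, had the highest level of the 7 topoisomerase genes at 41.0 ± 4.02 TPM (SD, n = 3). Top1, the type IB enzyme that relaxes supercoils in transcribed DNA, followed at 28.6 ± 2.44 TPM (n = 3). Top3b, which also acts on RNA, reached 6.61 ± 0.37 TPM, and Top2a, the type II enzyme of dividing cells, 4.13 ± 0.52 TPM. The mitochondrial enzyme gene Top1mt stood at 2.08 ± 0.19 TPM and Top3a at 0.58 ± 0.10 TPM. Spo11, a meiotic relative, had 1 read in replicate 1 and was listed at 0 in the others, where a count of 0 allows up to 0.043 TPM.

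Top2b exceeded Top1 in each library, by 0.52 ± 0.06 on the log2(TPM + 0.1) scale or a ratio of 1.44 ± 0.06 (exact sign-flip p = 0.25, n = 3). The size of this difference depended on how transcripts were combined: it was 1.63 with the planned sum over transcripts and 1.26 with the most abundant transcript. Relative to Top1, Top3b lay at -2.09 ± 0.18, Top2a at -2.76 ± 0.28, Top1mt at -3.72 ± 0.19 and Top3a at -5.41 ± 0.33, each with the same sign in the 3 libraries. With the planned sum these were -3.81, -2.14, -5.44 and -4.69, which turned the order of Top3b and Top2a and that of Top1mt and Top3a, and with a pseudocount of 1 Top3a lay at -4.23. On the GRCm38 assembly, Top2b (ENSMUSG00000017485.11) spans 16365179 to 16430787 on chromosome 14. Top1 (ENSMUSG00000070544.6) spans 160645888 to 160722764 on chromosome 2.

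**Figure D1:**
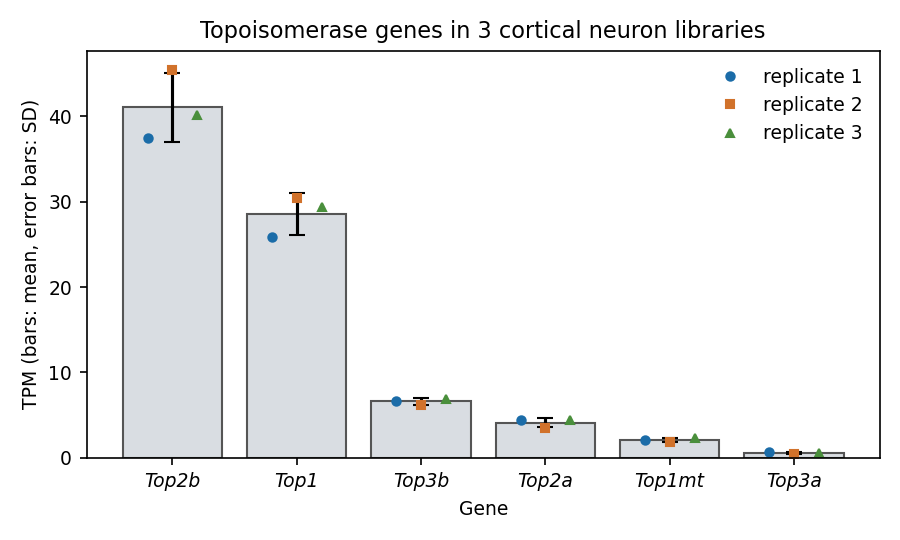
TPM of 6 topoisomerase genes, with bars for the mean, error bars for the SD and a symbol for each of the 3 replicates. Top2b (mean 41.0 TPM) and Top1 (28.6 TPM) stand above Top3b, Top2a, Top1mt and Top3a.

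Of 23 genes for partners and repair of trapped topoisomerases, 22 had a mean of at least 1 TPM. Parp1, a sensor of DNA breaks, reached 20.96 ± 1.51 TPM and Fmr1, the RNA-binding protein gene of fragile X syndrome, 19.5 ± 1.98 TPM. Tdp2, which removes trapped topoisomerase II from DNA ends, stood at 9.76 ± 1.07 TPM, and Rmi2 was lowest at 0.090 ± 0.031 TPM. Of 18 genes that resolve RNA-DNA hybrids, 15 were expressed, led by the helicase gene Ddx5 at 145 ± 11.4 TPM, Dhx9 at 35.7 ± 2.40 TPM and the splicing factor gene Srsf1 at 33.1 ± 1.69 TPM. Brca1 was lowest at 0.47 ± 0.07 TPM.

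Among 20 genes for cohesin, condensin and other chromosome architecture proteins, 19 were expressed. The cohesin gene Rad21 led at 34.2 ± 2.49 TPM, followed by Ncaph2 at 17.6 ± 1.26 and Stag2 at 14.3 ± 1.22 TPM. Ncapg, a condensin gene of dividing cells, was lowest at 0.77 ± 0.21 TPM. The 24 transcription elongation genes were each expressed, with the histone chaperone gene Ssrp1 at 36.2 ± 3.83 TPM, Supt5 at 26.3 ± 0.36, Paf1 at 22.6 ± 2.61 and Cdk12 lowest at 2.86 ± 0.17 TPM. Of 20 nucleosome remodelling and methyl-DNA genes, 19 were expressed, from H3f3b at 65.3 ± 1.04, H1f0 at 27.7 ± 1.42 and Smarca2 at 26.3 ± 0.47 TPM down to Dnmt3b at 0.11 ± 0.01 TPM. Among 10000 random lists of the same size, the median of the topoisomerase list ranked above 62.2%, partners and repair above 76.9%, RNA-DNA hybrid resolution above 82.7%, architecture above 93.2%, elongation above 99.7% and remodelling above 95.5%.

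The design text refers to gene length categories, and the next comparison asked how level varied with genomic gene length. Genes over 200 kb were more often expressed than genes under 10 kb. Of 5294 genes under 10 kb, 49.4 ± 0.23% reached 1 TPM per library, against 78.2 ± 0.91% of 958 genes over 200 kb. The median level was 0.92 ± 0.02 TPM under 10 kb, 3.14 ± 0.04 at 10 to 30 kb, 4.07 ± 0.08 at 30 to 100 kb, 4.27 ± 0.13 at 100 to 200 kb and 4.79 ± 0.33 TPM over 200 kb. Long genes with high levels included App, the amyloid precursor gene, at 421 ± 25.3 TPM, the synaptotagmin gene Syt1 at 232 ± 34.6 and the microtubule protein gene Map2 at 187 ± 13.8 TPM. Ppp3ca followed at 150 ± 19.3, Nell2 at 144 ± 7.30 and Ncald at 109.6 ± 4.52 TPM.

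The median of genes over 200 kb exceeded that of genes under 10 kb by 2.26 ± 0.12 log2 units (exact sign-flip p = 0.25, n = 3). Across 18202 nuclear coding genes, Spearman's rho between length and level was 0.19 ± 0.01, and genes are not independent replicates. Among the 11248 genes with a mean of at least 1 TPM the difference was -0.12 ± 0.14, smaller than the spread between libraries (exact sign-flip p = 0.50, n = 3), with a rho of -0.03 ± 0.02. Over all genes the difference was 1.09 with the span of the most abundant transcript as the length, 1.59 with a pseudocount of 1, 3.27 with the planned sum and 2.996 with 5 classes of equal size. Short genes held the highest nuclear values: Tmsb4x, an actin-binding peptide gene, at 1044 ± 30.5 TPM and the ferritin gene Fth1 at 868 ± 115 TPM. A model named Gm49450 was listed at 1029 ± 191 TPM. It overlaps the tubulin gene Tuba1a (678 ± 139 TPM) on the same strand of chromosome 15, so its value is uncertain.

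**Figure D2:**
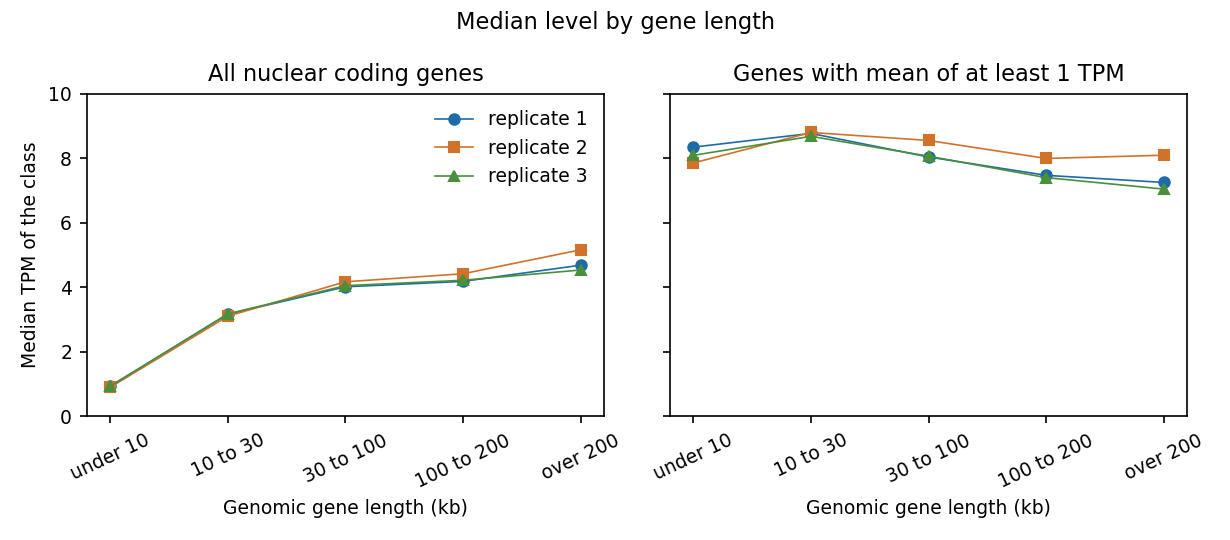
Median TPM of nuclear coding genes in 5 classes of genomic length in kb, over all genes (left) and over genes with a mean of at least 1 TPM (right), with a symbol per replicate. The left medians run from 0.92 to 4.79 TPM, and the right medians from 7.46 to 8.74 TPM.

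Marker lists were used to describe which cells the libraries held. Pan-neuronal genes were the highest of 11 lists, and the 15 members were each expressed. The microtubule regulator gene Stmn2 stood at 687 ± 55.6 TPM, the growth cone gene Gap43 at 458 ± 8.95 and the synaptic gene Snap25 at 373 ± 27.2 TPM, with Elavl4 lowest at 19.4 ± 4.21 TPM. All 10 excitatory and 11 of 12 inhibitory neuron genes were expressed. The glutamatergic genes Camk2a, Slc17a7 and Nrgn reached 130 ± 4.27, 89.98 ± 4.47 and 88.9 ± 3.98 TPM, and Neurod1 5.55 ± 0.86 TPM. The GABAergic genes Sst, Gad1 and Gad2 reached 106.5 ± 25.9, 84.6 ± 23.0 and 26.5 ± 6.92 TPM, and Pvalb 0.27 ± 0.15 TPM.

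Astrocyte genes were the second highest list, with 11 of 12 expressed. The glutamate transporter genes Slc1a3 and Slc1a2 stood at 184 ± 19.1 and 59.6 ± 5.45 TPM, Aldoc at 128 ± 21.4 and Gjb6 at 0.33 ± 0.05 TPM. The pan-neuronal median exceeded the excitatory median by 2.74 ± 0.14 and the inhibitory median by 3.50 ± 0.06 (4.34 with the planned sum over transcripts). It exceeded the astrocyte median by 2.15 ± 0.23 log2 units, a 4.45-fold difference (exact sign-flip p = 0.25, n = 3). The differences were 4.65 ± 0.33 for radial glia, 5.61 ± 0.25 for proliferation and 5.87 ± 0.33 for the oligodendrocyte lineage, with 10 of 11, 10 of 14 and 8 of 12 genes expressed. Fabp7, shared by radial glia and astrocytes, stood at 419 ± 81.4 TPM, Vim at 44.8 ± 6.78, Hopx at 27.6 ± 4.39 and the intermediate progenitor gene Eomes at 0.013 ± 0.017 TPM. Precursor genes of the oligodendrocyte lineage were measurable, with Olig1 at 34.4 ± 2.91, Olig2 at 15.95 ± 6.36 and Pdgfra at 11.6 ± 6.73 TPM, while the myelin gene Mobp stood at 0.018 ± 0.020 TPM.

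Cycling and non-neural cell types gave low values. Proliferation genes were led by Pcna at 8.36 ± 1.20, Top2a at 4.13 ± 0.52 and Ccna2 at 3.53 ± 0.35 TPM, with Ccnb1 at 0.61 ± 0.17 TPM. Pcna and Ccnb1 share sequence with other loci, with 44% and 36% unique 50-mers. The pan-neuronal median exceeded the pericyte and fibroblast, microglia, blood and endothelial medians by 7.50 ± 0.07, 8.21 ± 0.31, 9.21 ± 0.26 and 9.29 ± 0.23 log2 units. These sizes rest on the pseudocount and were 5.94, 6.15, 6.34 and 6.35 with a pseudocount of 1, where the oligodendrocyte and proliferation differences were 5.17 and 5.01. With the planned sum they were 8.27, 9.54, 10.9 and 10.6, and with members of at least 1 TPM only the pericyte, oligodendrocyte and radial glia differences were 5.46, 4.63 and 4.01. Of these lists, 4 of 10, 2 of 12, 0 of 5 and 0 of 10 genes were expressed, and their medians ranked above 9.37%, 4.84%, 5.71% and 0.41% of random lists. The pan-neuronal, excitatory, inhibitory and astrocyte medians ranked above 100%, 97.8%, 89.7% and 99.8%, and radial glia, proliferation and the oligodendrocyte lineage above 51.4%, 30.9% and 26.0%. Among microglial genes, Aif1 reached 1.03 ± 0.43 TPM, with Tyrobp at 0.46 ± 0.42 and Tmem119 listed at 0 in each library. Slco1a4, Kdr and Pecam1 stood at 0.77 ± 0.37, 0.37 ± 0.18 and 0.26 ± 0.04 TPM, and Cldn5 was listed at 0 in each library. Acta2, Dcn and Cspg4 reached 3.07 ± 0.85, 2.66 ± 0.74 and 1.49 ± 0.52 TPM, and Col1a2 0.073 ± 0.058 TPM. Cspg4 is also on the oligodendrocyte lineage list and is counted in both lists. Of blood genes, Hba-a1 and Hba-a2 stood at 0.14 ± 0.07 and 0.053 ± 0.027 TPM, and Slc4a1 was listed at 0 in each library. Hba-a1 and Hba-a2 had 22% and 27% unique 50-mers.

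**Figure D3:**
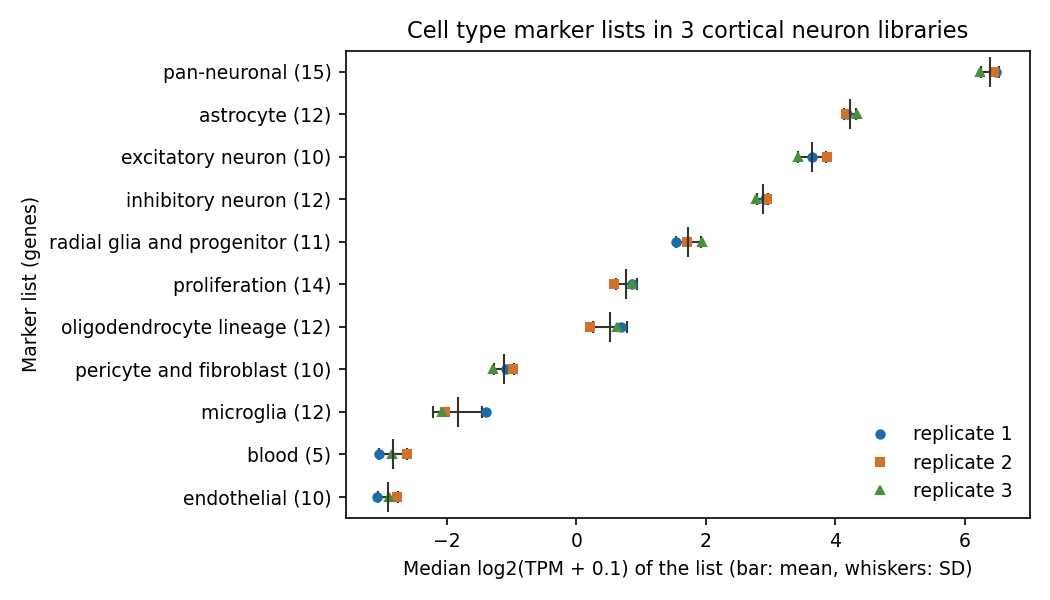
Median log2(TPM + 0.1) of 11 marker lists, with the number of genes in parentheses, a symbol per replicate, a bar for the mean and whiskers for the SD. Pan-neuronal genes (mean 6.38) lie above astrocyte genes (4.23), and endothelial genes are lowest (-2.91).

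Receptor and transporter pairs that change during neuronal maturation were compared inside each library. The NMDA receptor gene Grin2b, which prevails early, stood at 14.5 ± 2.79 TPM and Grin2a, which rises later, at 0.95 ± 0.20 TPM, a log2 difference of 3.81 ± 0.05 (exact sign-flip p = 0.25, n = 3). Restricted to transcripts whose reads came out whole, an alternative chosen after seeing the data, the difference was 2.54, and with a pseudocount of 1 it was 2.99. For both genes the transcript length is uncertain, and 56% of the 50-mers of Grin2a were unique. The chloride exporter gene Slc12a5 stood at 27.03 ± 3.07 TPM and the importer gene Slc12a2 at 8.29 ± 0.81 TPM, a Slc12a2 minus Slc12a5 difference of -1.69 ± 0.20, or -3.39 with the planned sum over transcripts. Scn2a (36.2 ± 5.50 TPM) exceeded Scn8a (11.2 ± 1.47 TPM) by 1.69 ± 0.03.

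Gad1 and Slc17a7 did not differ beyond the spread, at -0.12 ± 0.34 (exact sign-flip p = 0.75, n = 3). That difference was 2.33 with the planned sum over transcripts and 0.05 without replicate 3. Slc17a6, at 6.28 ± 1.23 TPM, lay -3.84 ± 0.27 from Slc17a7. Dcx, of young neurons, stood at 30.4 ± 1.58 TPM and Rbfox3, of mature neurons, at 37.8 ± 1.46 TPM, a difference of -0.31 ± 0.03, or -1.28 with the planned sum over transcripts.

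Synaptic genes were compared between textbook lists, called short and long here, and not by the length classes above. Snap25 and Calm2, on the short list, each span more than 10 kb. Whether length accounts for a difference between these lists was not tested. The median of 20 short synaptic genes exceeded that of 25 long synaptic and adhesion genes by 3.69 ± 0.14 log2 units, a 12.9-fold difference (exact sign-flip p = 0.25, n = 3). Calm2 reached 837 ± 47.5 TPM, Stmn3 424 ± 13.6 and Cfl1 413 ± 37.2 TPM, and Sncg 0.034 ± 0.015 TPM. Calm2 and Cfl1 had 66% and 65% unique 50-mers. Of the short genes 18 and of the long genes 24 were expressed, and their medians ranked above 100% and 97.8% of random lists. Among long genes, the scaffold gene Dlg2 stood at 69.5 ± 6.81, the adhesion genes Cdh13 and Opcml at 57.8 ± 4.01 and 54.1 ± 4.80, and Ctnna3 at 0.17 ± 0.03 TPM. The difference was 2.496 with the planned sum over transcripts.

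Ionotropic receptor and channel genes were expressed in most cases. Of 10 NMDA and AMPA receptor genes, 8 were expressed, with Gria2 at 71.9 ± 5.33, Grin1 at 66.7 ± 3.11, Gria1 at 57.3 ± 7.45 and Grin2c at 0.49 ± 0.06 TPM. The 12 GABA-A receptor genes were each expressed, with Gabra2 at 62.8 ± 8.26 (transcript length uncertain), Gabra5 at 53.6 ± 5.36 and Gabrd at 2.76 ± 0.54 TPM. Of 15 sodium and calcium channel genes, 14 were expressed, with Scn2b at 18.7 ± 3.68 and Scn9a at 0.076 ± 0.039 TPM. All 8 upper layer and 7 of 8 deep layer genes were expressed, and the upper layer median was higher by 1.09 ± 0.24 log2 units (exact sign-flip p = 0.25, n = 3). This difference was not recomputed under the alternatives. Whether the members of these textbook lists are restricted to their layers was not tested, so it need not reflect layer identity. Upper layer genes were led by Mef2c at 121 ± 23.0 (transcript length uncertain), Lhx2 at 29.1 ± 1.22 and Cux1 at 19.8 ± 1.4 TPM, with Rorb at 2.24 ± 0.56 TPM. Deep layer genes were led by Ntsr1 at 8.60 ± 0.22, Tbr1 at 7.20 ± 0.90 and Tle4 at 7.12 ± 1.33 TPM, with Foxp2 at 0.44 ± 0.10 TPM. Of 15 genes listed under other brain regions, which need not be absent from cortex, 4 were expressed. These included Calb2 at 16.96 ± 0.32, Zbtb20 at 1.92 ± 0.24 and Ppp1r1b at 1.58 ± 0.11 TPM. Hoxc6 was listed at 0 in each library. Against random lists, the medians ranked above 99.2% for NMDA and AMPA receptors, 99.99% for GABA-A receptors, 93.1% for channels, 95.8% for upper layers, 75.99% for deep layers and 4.79% for other regions.

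Of 14 immediate early genes, 13 were expressed, and 13 were higher in replicate 3 than in both others, as were 31.5% of all expressed genes. The exception was Fosl2 at 7.58, 7.12 and 5.99 TPM in replicates 1, 2 and 3. Egr1 stood at 16.8, 15.8 and 21.2 TPM, Jun at 8.66, 8.28 and 12.6 and Egr3, of uncertain transcript length, at 13.2, 15.2 and 20.6 TPM. Counted after the data were seen, 14 of 15 pan-neuronal and 9 of 11 expressed inhibitory neuron genes were lowest in replicate 3, as were 6 of 10 excitatory genes. The share of all expressed genes that were lowest there is not given here. Of the other marker lists, 6 of 8 oligodendrocyte lineage, 6 of 10 proliferation, 6 of 11 astrocyte, 4 of 10 radial glia, 2 of 4 pericyte and 1 of 2 microglial genes were highest there. These counts are to be read beside the 31.5% of all expressed genes. Functional lists besides the immediate early and p53 lists were not counted by member. Their replicate 3 medians minus the mean of replicates 1 and 2 ran from -0.34 (deep layer) to 0.33 log2 units (ribosomal protein). Chromosome architecture lay at 0.17 and integrated stress at 0.08. Gad1 stood at 84.9, 107.5 and 61.5 TPM and Pdgfra at 11.5, 4.96 and 18.4 TPM. Fosb was lowest at 0.52 ± 0.23 TPM. The 12 p53 response genes were each expressed, with Ccng1 at 32.2 ± 2.80, Bax at 32.1 ± 4.50, Cdkn1a at 14.6 ± 1.15 and Eda2r at 1.89 ± 0.11 TPM. All 10 integrated stress response genes were expressed, among them Atf4 at 173 ± 9.25, Asns at 98.3 ± 5.98, Hspa5 at 93.2 ± 8.12 and Atf3 at 1.45 ± 0.40 TPM. Atf4, Asns, Hspa5 and Atf3 were each highest in replicate 3, and the other members of that list were not counted. None of the named p53 genes was highest there. Of 12 interferon response genes, 1 was expressed. Ifitm3 stood at 0.68 ± 0.14 TPM, Ifit3 at 0.41 ± 0.18 and Oas1a listed at 0 in each library. Ifit3 and Oas1a had 49% and 45% unique 50-mers. Against random lists, the immediate early, p53, integrated stress and interferon medians ranked above 67.6%, 95.05%, 99.9% and 2.41%.

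The highest coding values belonged to the mitochondrial genome, with mt-Nd1 at 2574 ± 132, mt-Co1 at 2462 ± 138, mt-Cytb at 2336 ± 115, mt-Nd2 at 1788 ± 83.9 and mt-Nd5 at 1249 ± 10.8 TPM. In the same list mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 were listed at 0 in each library, with at most 3.33% unique 50-mers. Levels of genes with near-identical copies are therefore uncertain. Of 20 ribosomal protein genes all were expressed, and of 12 housekeeping genes 10, and both medians ranked above 100% of random lists. Among ribosomal protein genes, Rplp1 stood at 488 ± 44.7, Rpl32 at 224 ± 39.5, Rpl4 at 214 ± 11.5 and Rpl3 at 1.15 ± 0.17 TPM. Among housekeeping genes, Eef1a1 stood at 577 ± 63.3, Actb at 396 ± 48.1, Tubb5 at 264 ± 33.3 and Ppia at 0.85 ± 0.07 TPM.

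By annotated class, protein-coding genes held 87.9 ± 0.46% of the summed gene values, and 11260 of 18219 had a mean of at least 1 TPM. At that level were also 119 of 1471 lincRNA genes, 79 of 1527 antisense genes and 147 of 3266 pseudogenes. Mitochondrial genes held 5.89 ± 0.15% and annotated microRNA genes, with Mir6236 at 3499 TPM among them, 3.41 ± 0.22% of the values. These shares are of values of 1 transcript per gene. Of the TPM over all transcripts, mitochondrial rows held 1.46%, 1.42% and 1.46% in replicates 1, 2 and 3. Across 18213 coding genes, Pearson's r between libraries was 0.997 for replicates 1 and 2 and 0.996 for the other pairings, computed across genes. The median SD over libraries was 0.12 log2 units for genes at 1 to 10 TPM and 0.10 at 10 to 100 TPM, against 0.059 and 0.027 from counting alone.

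The largest spread among expressed coding genes was in Aldh1a7, an aldehyde dehydrogenase gene, at 2.24, 2.59 and 0.16 TPM in replicates 1, 2 and 3. Adora2b, an adenosine receptor gene, stood at 1.81, 1.71 and 0.44 TPM, and the agouti coat colour gene a at 1.19, 1.5 and 5.33 TPM. These values rest on 171, 136 and 37 reads for Adora2b and on 32, 34 and 128 reads for a. Cwc22, a splicing factor gene with 59% unique 50-mers, stood at 6.45, 18.1 and 31.5 TPM. The ribosomal protein genes Rpl26 (15.6, 2.5 and 11.6 TPM) and Rpl35a (35.7, 28.6 and 9.15 TPM) had 51% and 34% unique 50-mers.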

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

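The tests here were chosen after the result was seen, except those on genes that escape X inactivation and on GC content and length over both stress lists. The design has 1 group, so no biological explanation by group was tested.

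Rows outside the comparisons carried signal above what a count of 0 allows. Rows with no match in the newer annotation held 1.99 ± 0.05% of all TPM (SD, n = 3). Mir6236, a row of 123 bp annotated as a microRNA gene, lies on chromosome 9 from 110281287 to 110281409. It stood at 3356, 3005 and 4136 TPM in replicates 1, 2 and 3, a mean of 3499 TPM. The limit for a count of 0 was 0.564 TPM. Uniqueness was measured for coding genes only, so the source of these reads is uncertain and they need not come from a microRNA.

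Some genes that every cell uses were listed at or near 0. The tables argue against poor recovery of mitochondrial RNA, since the 5 mitochondrial genes with over 90% unique 50-mers had a median of 1788 TPM. Reads shared with near-identical copies are a candidate explanation: the 4 mitochondrial genes at 0 had at most 3.33% unique 50-mers, and the 7 others at least 37.6%. Across 32 ribosomal protein and housekeeping genes, Spearman's rho between unique share and level was 0.49 (Pearson's r 0.49, permutation p = 0.0049, 1 relation computed, genes not independent). Ppia, at 0.85 TPM with 39% unique 50-mers, and Rpl19, at 58.1 TPM with 10%, show that the share alone does not set the level.

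Y-linked genes and Xist, the RNA that coats the inactive X, differed between libraries. Xist stood at 14.99, 40.5 and 34.4 TPM and Eif2s3y at 27.7, 11.5 and 19.2 TPM in replicates 1, 2 and 3. Depth is argued against, since Xist lay at -1.43 log2 units in replicate 1 relative to replicate 2 while 4 Y-linked genes lay above 0. Different proportions of male and female cells are a candidate explanation: the 4 Y-linked differences lay within 0.43 of each other. In the test fixed beforehand, the escape genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x had a median replicate 2 minus replicate 1 difference 0.26 above that of 384 other expressed X-linked genes, with 4 of 4 above 0.

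Replicate 3 was noticed for higher medians of the immediate early and p53 lists. The p53 part did not hold by member: 5 of 12 genes were higher in replicate 3 than in both others, with a median shift of 0.08. Over both lists, depth is argued against, at 98.4% of that of replicate 2, but GC content and length stay open (shift 0.301 ± 0.133 bootstrap SE after their trend was removed, against a bound of 0.3 to which the SE was added after the value was seen), and so does a larger astrocyte share (members minus astrocyte markers 0.22, permutation p = 0.21). For immediate early genes alone, a narrowing made after the members were seen, the shift after removing that trend was 0.449 ± 0.036, and the shift before removing it was 0.51, which lay 0.41 above that of astrocyte markers (permutation p = 0.0045). The bootstrap SE and permutation p values are taken over genes, which are not independent, and do not measure spread between libraries. For the 13 expressed immediate early genes, the shift left after removing the trend speaks against GC content and length as the whole cause. The comparison with astrocyte markers does not decide, since the immediate early list was singled out after its members were seen. Apoe and Cst3, abundant in astrocytes and outside the marker list, shifted by 0.63 and 0.53, above the 0.51 of the immediate early genes. The listed Gja1 and Aldoc shifted by 0.43 and 0.39. A larger astrocyte share therefore stays open, as does a different mix of cell types. In replicate 3, 14 of 15 pan-neuronal and 9 of 11 inhibitory genes were lowest, the share over all expressed genes not being given. There, 6 of 8 oligodendrocyte lineage genes were highest, against 31.5% of all expressed genes. Neither that mix nor handling of the culture was tested.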

How the results depend on the processing

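The main gene value and 2 alternatives, genes with at least 90% unique 50-mers and transcripts with whole reads, were chosen after seeing the data. Of 244 recomputed values of 24 differences, 239 kept their sign and 5 turned. With the planned sum over transcripts, which counts reads repeatedly, Gad1 minus Slc17a7 was 2.33 and the length difference among expressed genes was 0.30. Top2b minus Top1 kept its sign, at 1.63. Leaving out each replicate gave -0.298 to 0.046 for Gad1 minus Slc17a7, with 0.046 without replicate 3. With genes of at least 1 TPM only, the length difference was -0.12 and its rho -0.028. Keeping genes by the level that is compared lowers the difference by construction, so these values alone do not show its cause. With exonic lengths of 1 to 5 kb, the difference among expressed genes was 0.083; the cause was not tested. The mean Pearson's r of 0.996 became 0.997 and 0.989 with pseudocounts of 1 and 0.01 and 0.991 at 1 TPM or more. At a minimum of 5 TPM, 7451 of the 11260 coding genes passed, fewer by construction. The rho of divergent neighbours was 0.035 with both genes expressed. The ranges without each replicate were 0.49 to 0.56 for Top2b minus Top1, 3.79 to 3.84 for Grin2b minus Grin2a, 2.08 to 2.29 for pan-neuronal minus astrocyte, 3.61 to 3.73 for short minus long synaptic genes, 2.19 to 2.31 for length and 11244 to 11264 expressed genes. Rescaling nuclear coding values multiplied all of them within a library, so the short synaptic median went from 6.76 to 8.97. Isoform use and its alternatives were not run, since overlapping transcripts share reads. No paired analysis was possible because there is only 1 group. With 3 libraries no sign-flip test over libraries could pass 0.05. At 0.1 to 1 TPM the median SD was 0.21, against 0.22 from counting. The pseudocount of 0.1 lowers the first value at such levels but not the second, so they cannot be compared directly.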

Other observations

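The tests on gene length, on neighbouring genes and on autosomal pairs were chosen after the result was seen, although what the length test among genes with unique 50-mers would show was written down before its value was computed.

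The noncoding genes named here, which leave out microRNA genes, were chosen after their values were seen. Their uniqueness was not measured, so the source of their reads is uncertain. Among the highest were the models Gm42418 at 229.9 ± 71.5 and Gm15564 at 166 ± 33.3 TPM. Rian and Meg3, maternally expressed RNAs of an imprinted cluster on chromosome 12, stood at 249 ± 27 and 151 ± 19.3 TPM (SD, n = 3). Malat1, a nuclear RNA, stood at 43.0 ± 4.95, Pantr1 at 47.2 ± 3.93, Miat at 29.8 ± 2.82 and Tug1 at 20.9 ± 2.67 TPM. The growth-arrest RNA Gas5 stood at 32.2 ± 5.87 and Snhg6 at 17.7 ± 2.49 TPM.

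A larger share of unexpressed genes among short genes is a candidate explanation for the higher median of genes over 200 kb. Of genes under 10 kb 49.5% had a mean of at least 1 TPM, against 78.2% over 200 kb. The difference was -0.12 among expressed genes, but keeping genes by the level that is compared lowers it by construction, so it does not decide alone. Among expressed genes the median and 95% point were 8.09 and 92.52 TPM under 10 kb, and 7.46 and 54.01 TPM over 200 kb. An equal upward shift of all long genes is therefore argued against, since their upper levels were not higher. Loss of reads from short genes with copies elsewhere is argued against: the difference was 2.01 among genes with at least 90% unique 50-mers.

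A hypothesis drawn from the series title was that adjacent genes share levels according to orientation. Over all adjacent coding pairs, Spearman's rho was 0.13 for 3992 divergent, 0.079 for 3721 convergent and 0.22 for 8574 tandem pairs, each above the highest of 1000 shuffles within length classes. With both genes expressed, divergent pairs gave 0.035, inside the shuffled 95% range (up to 0.048), convergent pairs 0.013, also inside it (up to 0.052), and tandem pairs fell by 0.18 to 0.040, above it (up to 0.034). Keeping genes by level narrows its range and lowers rho whatever the cause, so these values leave open both a relation between expressed divergent neighbours and clusters of unexpressed genes. For pairs less than 5 kb apart, rho was 0.13 for divergent (shuffled 95% range up to 0.067), 0.12 for tandem (up to 0.050) and -0.016 for convergent pairs, the last inside its range. No difference between orientations was tested. Pairs are not independent replicates.

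Strain or litter differences at linked genes could give neighbouring genes a large spread between libraries. Among the 108 genes in the top 1% by spread, 5 neighbouring pairs were found, above the 95% range of random draws, up to 3, which met the criterion fixed beforehand. However, 4 of these pairs are on the Y chromosome, whose genes differed between libraries. On the autosomes 1 pair was found, S100a1 and S100a13, and the median of random draws was also 1. The test thus gives no evidence for linked strain differences, and differences at single genes such as Aldh1a7, Cwc22 and a stay open.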
